A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

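Total RNA of Saccharomyces cerevisiae was compared on 4 arrays with 2 channels each, per the labels. Channel 1 held RNA of the temperature-sensitive abf1-1 mutant and channel 2 held RNA of wild type cells. Both strains were grown in rich medium at 30 °C to an OD600 of 1.0 to 1.2, an equal volume of medium at 42 °C was added, and cells were collected after 45 min at 36 °C, per the labels. All 4 arrays form 1 group, numbered 1 to 4 as in the labels. The labels do not say whether the 4 arrays came from separate cultures. The p-values of single features thus measure only the spread between these arrays, which may be technical. Those of gene lists tested with a preset correlation, of permutations and of the binomial test rest on the spread over genes or features. They do not measure how far a list varies between arrays. The dyes, the scanner, the background correction and the normalization are not given in the sources used here.

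The table deposited by the authors held 1 log ratio per probe and array, taken here as log2 because the values have both signs and lie between -4.30 and 2.67. The log base and the numerator of the ratio are stated neither by the labels nor by the table, so signs are given as deposited, and neither set of genes is called higher in the mutant. If the base were another, all values would change by 1 common factor, as would counts that use a fold limit, such as treat, the minimum of 1.5-fold and counts at 2-fold, while tests against 0 would not change. The medians of the deposited columns were -0.01, 0.03, -0.03 and 0.02 on arrays 1 to 4, close to 0, and whether the ratios had been centred before deposit is not given in the sources used here. The table had 6226 probes and 0 missing values, and 0 columns without a sample. On each array 1 exact value was shared by many probes, 41, 46, 41 and 35 of them, and 52 probes carried such a value on at least 1 array. What that value stands for is not given in the sources used here. No counts or spot brightness came with the ratios, so the number of arrays limits the precision.

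Probes were named through the platform annotation, which gave 5576 probes 1 gene, 0 probes several genes and 650 probes none. Symbols were matched with the RefSeq gene table of assembly R64, from which 4 probe identifiers were absent. That table was used only for names, for gene length and for the order and overlap of neighbouring genes. Each array was centred on its median, and the probes of a gene were averaged, which touched 36 genes. This left 6189 features, of which 5539 were named genes.

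The ratio of each feature was tested against 0 with the lmFit and eBayes functions of limma 3.58.1 in R 4.3.3, with an intercept only, 3 residual degrees of freedom and Benjamini-Hochberg adjustment over all features, two-sided. Features with an adjusted p below 0.05 are called here. Gene lists were tested with camera of the same package against all other features, with a preset correlation of 0.01 and adjustment over the 33 lists, and again with the correlation estimated per list. With an estimated correlation camera uses only the residual degrees of freedom of the fit, 3 here, so that test has little power. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

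The group, the tests, the 33 gene lists, the rule for the genes named and a set of other settings were fixed before the data were examined. The rule took, among called genes with the same sign on all 4 arrays, the 14 largest positive and the 14 largest negative mean ratios, ABF1, and from each list up to 4 called members with the largest mean ratio either way, or 2 members given as values where none was called. Genes and probes named outside it were chosen after their values were seen. The lists cover reported Abf1 targets, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, heat shock chaperones, the general stress response, the proteasome, respiration, the tricarboxylic acid cycle, glycolysis, amino acid, methionine, purine, ergosterol and lipid synthesis, the phosphate and iron regulons, cell wall stress, the unfolded protein response, histones, 3 phases of the cell cycle, replication origin factors, silencing, meiosis, both mating types, pheromone response, strain markers, subtelomeric families and secretion. They were recalled from textbook knowledge and not chosen on these arrays.

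These other settings were no centring, equal spread, quantile normalization, other minimum numbers of arrays, array weights, robust eBayes, an adjusted p below 0.01, a minimum of 1.5-fold, treat against 1.2-fold, medians, single probes, each array left out, estimated correlations, ranks and fry. After the correlations between arrays had been seen, a term for arrays 1 and 3 against arrays 2 and 4 was added, which leaves only the spread within the pairs as the error, as were fits within each pair, turned signs of arrays 2 and 4, fry with that term, lists without ABF1, a fit without the probes at a shared value and removal of the trend on gene length within each array. The planned test of genes with an Abf1 site upstream needs a genome sequence, and was not run. The planned test of genes near chromosome ends by distance was not run either, although the gene table held gene starts and ends. A set by gene order took its place.

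The fits were tested on simulated data of 6189 features with the split of the arrays kept, 200 changed genes and 10 simulations. Without the pair term, 0.8% of changes of 0.5 on the log2 scale were recovered, 56% of changes of 1, 79.2% of changes of 1.5 and 91.8% of changes of 2, and 0.259% of calls were unchanged genes. With the pair term the shares were 56.8%, 90.4%, 95.6% and 98.8%, and 4.06% of calls were unchanged genes. The simulated split was equal and opposite in the pairs, so it cancelled in the mean of an unchanged gene. Without the pair term the simulated split only widened the error, which held the share of 0.259% down. Where real differences between the pairs do not cancel, the share of false calls is not known for either fit. A list of 40 genes shifted by 0.30 was found in 10 of 10 simulations and an unshifted list in 0 of 10, in both fits. Simulated genes varied independently, with the split dealt to them at random, so members of a list were not correlated. In the data the estimated correlation was 0.68 for cytosolic ribosomal proteins and 0.47 for meiosis. The simulations therefore do not show how often such correlated lists pass without a shift.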

Results

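ABF1 encodes an essential general regulatory factor that binds promoters, replication origins and silencers. The arrays address which transcripts differ between cells with the temperature-sensitive abf1-1 allele and wild type cells after a shift to 36 °C. Each of the 4 arrays set RNA of the mutant against RNA of wild type, so every value is a ratio within an array, with 6226 probes per array and an SD over probes of 0.49, 0.59, 0.49 and 0.50 on arrays 1 to 4. The sources used here do not say which strain stands in the numerator, and ratios are called positive or negative as deposited.

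The ABF1 transcript itself (YKL112W) had a positive log2 ratio of 1.62 ± 0.43 (SD, n = 4), with 0.99, 1.69, 1.96 and 1.82 on arrays 1 to 4. It passed the limma test with an adjusted p of 0.0254, and with a term for the pair of arrays at 0.00055. With any 1 array left out and no pair term the adjusted p lay between 0.0607 and 0.188, and with the signs of arrays 2 and 4 turned the mean was -0.14. It ranked 4 of 5539 named genes by mean ratio, and 3488 by the size of the mean, whatever its sign, with those signs turned. The allele changes the protein and is no deletion, so this level does not check the labels.

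The arrays fell into pairs. Across probes, which are not independent replicates, the log2 ratios of arrays 1 and 3 correlated with a Pearson r of 0.742 and those of arrays 2 and 4 with 0.864. Between the pairs r was -0.103, 0.05, -0.221 and -0.113. SWI4, which encodes the DNA-binding part of the SBF transcription factor, had -0.76 and -0.90 on arrays 1 and 3 and 1.60 and 1.63 on arrays 2 and 4, and SIR4, which encodes a silencing protein, had -1.37 and -1.71 against 1.92 and 1.20. The ratios of 1926 features, or 31.1%, had the same sign on all 4 arrays, and 33% would be met if the pairs were unrelated, given that 80.4% had 1 sign on arrays 1 and 3 and 82.2% on arrays 2 and 4. The share of same signs was thus not above chance. The labels name no batch or dye swap that would part the arrays this way.

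**Figure D1:**
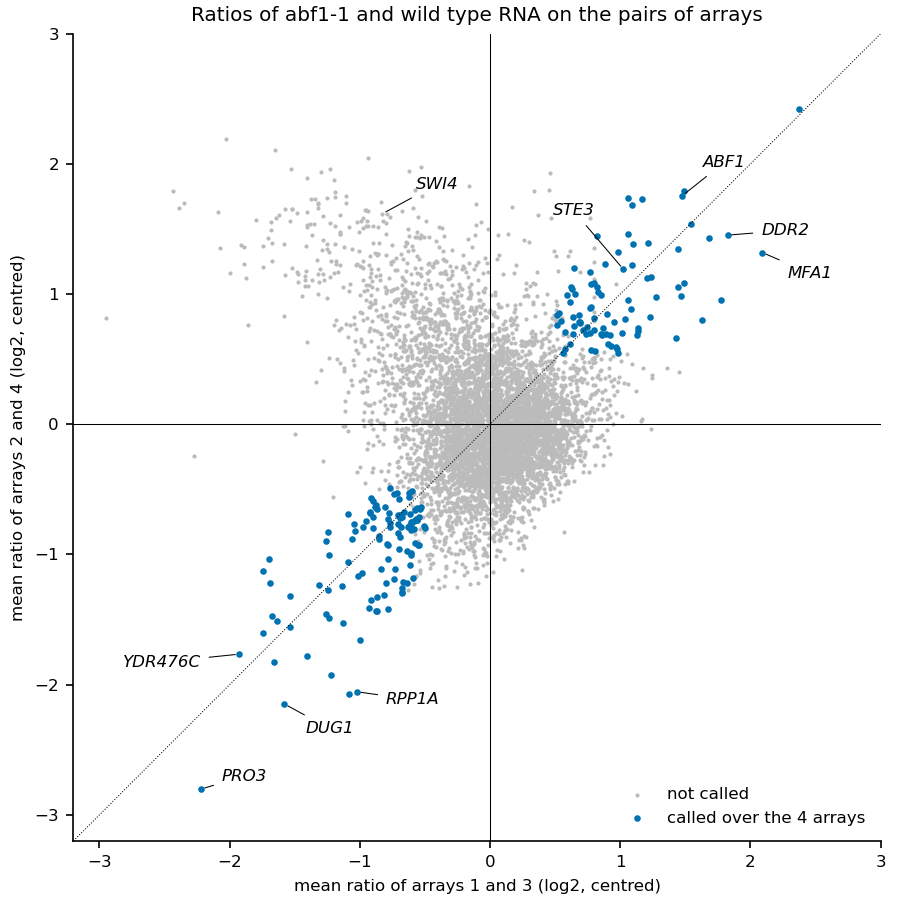
Each point is 1 of 6189 features, with its mean log2 ratio on arrays 1 and 3 on the horizontal axis and on arrays 2 and 4 on the vertical axis, both centred on the array median. The 200 features called over the 4 arrays (blue) lie in the lower left and upper right, while SWI4, at -0.83 and 1.62, lies with features of opposite sign in the upper left; the dotted line marks equal ratios.

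Over the 4 arrays, 200 of 6189 features were called, 85 with positive and 115 with negative ratios. The fit behind these calls takes the 4 arrays as independent, although they fall into pairs. Its p-values may thus be too small, and the count of 200 too large. All 200 had the same sign on all 4 arrays, which a call at this threshold on 4 values all but requires. The median log2 ratio was 0.88 for the positive calls and -0.85 for the negative ones. With a term for the pair of arrays 2021 features were called, 1031 positive and 990 negative, and these included all 200. That fit measures the mean of the pairs against the spread within them and takes no account of disagreement between the pairs: of the 2021, 368 had pair means of opposite sign, SWI4 among them (adjusted p 0.00873), and 1421 had the same sign on all 4 arrays. Without array 1, 3 or 4 limma called 0 features, and without array 2 it called 22, with 898, 1066, 752 and 1016 features at an unadjusted p below 0.05 without arrays 1, 3, 4 and 2. With the signs of arrays 2 and 4 turned, 302 features were called, 301 of them negative, and 0 of these were among the 200.

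Among the positive ratios were genes of stress and of mating. MFA1, a gene for the precursor of the mating pheromone a-factor, had 1.71 ± 0.50 (SD, n = 4; adjusted p 0.0271), and AFB1, which encodes a barrier protein for that pheromone, had 1.56 ± 0.30. The stress-induced genes DDR2, HSP12, SSA4 and HSP26 had 1.64 ± 0.30, 1.37 ± 0.47, 1.25 ± 0.24 and 1.21 ± 0.50. HSP32 had 1.23 ± 0.34, but its near-identical paralogs may share its probe. LEU2, an enzyme gene of leucine synthesis that is widely used as a selection marker, had 1.18 ± 0.11. PES4 and RNP1, which encode proteins with RNA-binding domains, had 1.64 ± 0.18 and 1.45 ± 0.33. ULI1, SPG4 and the uncharacterised YER187W had 1.39 ± 0.34, 1.26 ± 0.34 and 1.40 ± 0.45. Among these genes the means of the pairs lay farthest apart for HSP26 (1.63 on arrays 1 and 3, 0.80 on arrays 2 and 4), HSP12 (1.77 and 0.96) and MFA1 (2.09 and 1.32). Limma's adjusted p of these 13 genes lay between 0.0104 and 0.0452.

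Among the negative ratios PRO3, the gene for the enzyme of the last step of proline synthesis, had the largest at -2.51 ± 0.34 (SD, n = 4), a 5.70-fold difference with a limma adjusted p of 0.0104. DUG1, for a dipeptidase of glutathione breakdown, had -1.86 ± 0.35, and IPP1, for inorganic pyrophosphatase, had -1.74 ± 0.33. The ribosome biogenesis gene RIX7 had -1.67 ± 0.18, the ribosomal stalk gene RPP1A -1.54 ± 0.60 and the ribosome rescue gene HBS1 -1.55 ± 0.18. NHX1, for an endosomal sodium and proton exchanger, had -1.58 ± 0.16, SEC53, for phosphomannomutase, had -1.57 ± 0.44, EMC3, of the endoplasmic reticulum membrane complex, had -1.45 ± 0.28, and DSS4 had -1.59 ± 0.23. YEN1, for a Holliday junction resolvase, had -1.58 ± 0.58, NIT3 had -1.44 ± 0.38, and YDR476C and YPR172W had -1.85 ± 0.10 and -1.43 ± 0.15. The means of the pairs lay farthest apart for RPP1A (-1.02 on arrays 1 and 3, -2.05 on arrays 2 and 4) and YEN1 (-1.08 and -2.07). Of the 200 calls, 22 were probes without a gene name, such as probe 3626 at 2.40 ± 0.25 and probe 4964 at -1.57 ± 0.19.

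**Figure D2:**
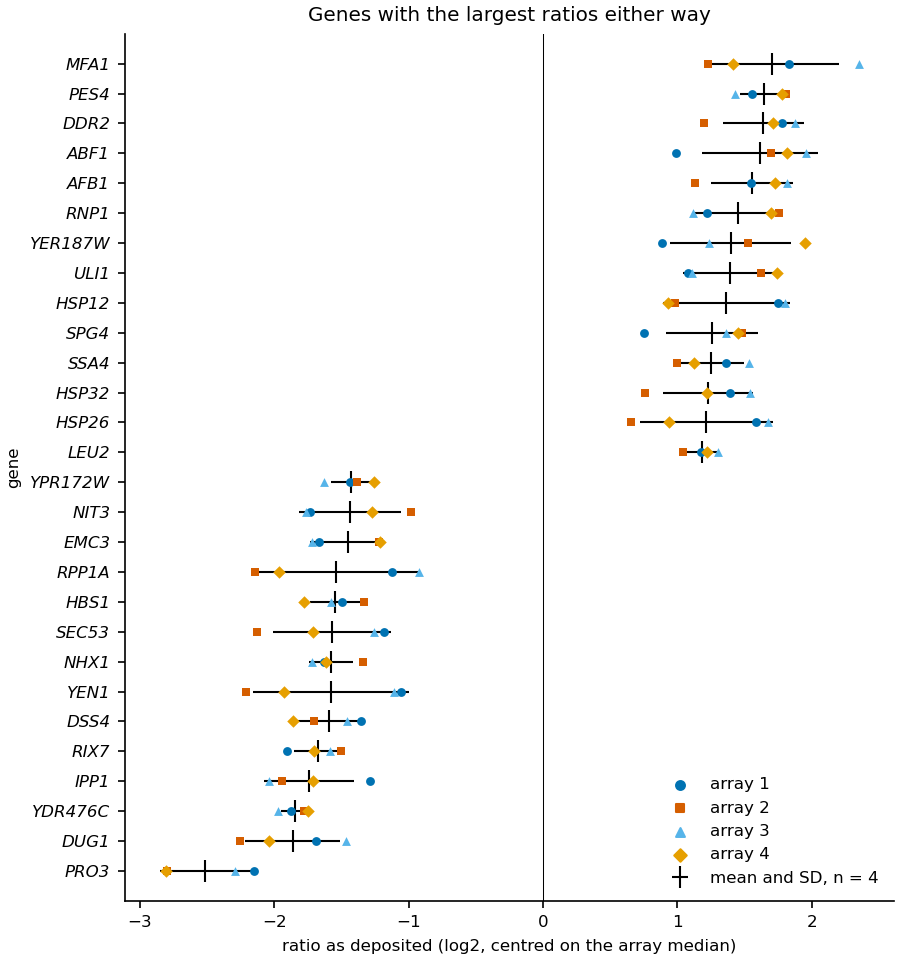
The 14 genes with the largest positive and the 14 with the largest negative mean log2 ratio among called genes are shown with the ratio on each array (coloured symbols), the mean (vertical bar) and the SD of 4 arrays (horizontal line). The rule took only genes with the same sign on all 4 arrays, and their means run from MFA1 at 1.71 to PRO3 at -2.51.

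The lists of cytosolic ribosomal proteins and ribosome biogenesis had negative means. Of 133 measured genes for cytosolic ribosomal proteins, 130 had a negative mean ratio, with a list mean of -0.46 ± 0.39 (SD of 4 array means), -0.14 on arrays 1 and 3 and -0.77 on arrays 2 and 4. Of these, 4 were called, all negative: RPP1A, RPP0 (-0.96), RPL9A (-0.81) and RPL19B (-0.59), and 29 passed when adjusted over the list alone. Of 58 ribosome biogenesis genes, 3 were called, all negative: RIX7 and the nucleolar genes NOP56 (-0.70) and CBF5 (-0.65), and 5 passed when adjusted over the list alone. The mean of that list was -0.20 ± 0.14, with -0.07 on arrays 1 and 3 and -0.32 on arrays 2 and 4. Camera's adjusted p was 8.85e-21 for the ribosomal proteins and 4.15e-05 for ribosome biogenesis, and with the term for the pair of arrays 6.47e-27 and 5.86e-05. Neither passed with an estimated correlation, where camera's adjusted p was 0.626 for both. The estimated correlations were 0.68 and 0.26, far above the preset 0.01, so the p-values with the preset overstate the evidence for these lists. With 3 residual degrees of freedom the test with an estimated correlation also has little power. Both lists passed in the opposite direction with the signs of arrays 2 and 4 turned, at 0.32 (adjusted p 1.31e-08) and 0.12 (0.00153).

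Of 5 lists of biosynthesis genes, those of amino acid and ergosterol synthesis passed with negative means and the preset correlation, and those of purine, methionine, and fatty acid and phospholipid synthesis did not pass. Neither of the lists that passed did so with an estimated correlation, where the adjusted p was 0.626 for amino acid synthesis and 0.699 for ergosterol. Of 46 amino acid synthesis genes, most of them activated by Gcn4, 38 had negative means and 4 were called, all negative: TRP3 at -1.26 ± 0.16, ARO3 at -1.13 ± 0.30, ARO4 at -0.74 ± 0.24 and ILV6 at -0.65 ± 0.18 (SD, n = 4). Adjusted over the list alone, 5 passed. The list mean was -0.24 ± 0.14, -0.13 on arrays 1 and 3 and -0.35 on arrays 2 and 4. Of 23 ergosterol genes 21 were negative and ERG28 was called at -0.86 ± 0.18, with 2 genes passing when adjusted over the list alone. The mean of -0.28 ± 0.33 came from arrays 2 and 4 (-0.55), with -0.01 on arrays 1 and 3. Camera's adjusted p was 9.62e-06 for amino acid synthesis and 0.000448 for ergosterol, and with the pair term 2.74e-05 and 9.61e-05. Without array 2 the ergosterol list missed the threshold, with an adjusted p of 0.0781. With the signs of arrays 2 and 4 turned both lists passed in the opposite direction, amino acid synthesis at 0.11 (adjusted p 0.0362) and ergosterol at 0.27 (0.000183).

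The list of general stress genes had a positive mean on every array, though not every member did. Of 38 genes driven by Msn2 and Msn4, 32 had positive and 6 negative means, 6 were called, all positive, and 14 passed when adjusted over the list alone. Beside DDR2, HSP12 and HSP26 the aldehyde dehydrogenase gene ALD3 was called at 0.87 ± 0.11 (SD, n = 4). The list mean was 0.37 ± 0.07, with 0.41 on arrays 1 and 3 and 0.34 on arrays 2 and 4 (camera adjusted p 3.22e-07, with the pair term 3.22e-06, and 0.626 with an estimated correlation). The 30 heat shock chaperones were not shifted as a list, with a mean of 0.10 ± 0.12 and an adjusted p of 0.764, although HSP12, SSA4 and HSP26 were called and 5 positive and 3 negative genes passed when adjusted over the list alone. Of 15 genes of the unfolded protein response, INO1 was called at 0.83 ± 0.26, 4 passed when adjusted over the list alone, and the mean was 0.28 ± 0.16, with 0.41 and 0.16 in the pairs (adjusted p 0.0134, with the pair term 0.01, 0.0569 without array 3, and 0.626 with an estimated correlation). INO1 is a phospholipid synthesis gene, and the chaperone gene KAR2 had 0.21 ± 0.57 and was not called. Neither list passed with the signs of arrays 2 and 4 turned, with a mean of 0.04 (adjusted p 0.395) for general stress and 0.13 (0.151) for the unfolded protein response.

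Of 3 lists of mating genes, the a-specific list and the haploid and pheromone list passed with positive means and the preset correlation, and the alpha-specific list did not pass. With an estimated correlation neither of those that passed did, with an adjusted p of 0.626 for both. All 7 genes specific to a cells had positive means, MFA1 and the agglutinin subunit gene AGA2 (0.74 ± 0.11, SD, n = 4) were called, and 3 passed when adjusted over the list alone. The list mean was 0.63 ± 0.16, with 0.74 and 0.52 in the pairs (camera adjusted p 0.000962, with the pair term 0.000748). Of 4 genes specific to alpha cells, STE3, the receptor gene for a-factor, was called at 1.11 ± 0.11, while MF(ALPHA)1 had 0.66 ± 0.73, SAG1 0.23 ± 0.16 and MF(ALPHA)2 -0.59 ± 0.21. That list did not pass (mean 0.35 ± 0.22, adjusted p 0.254), and 1 positive and 1 negative gene passed when adjusted over the list alone. Of 19 haploid and pheromone genes 15 had positive and 4 negative means, the agglutinin gene AGA1 was called at 1.06 ± 0.24 and 3 passed when adjusted over the list alone. Its mean was 0.29 ± 0.22, with 0.10 and 0.48 in the pairs (adjusted p 0.044, with the pair term 0.0212, 0.051 with ratios not centred, and up to 0.117 without array 2 or array 4). The a-specific mean with the signs of arrays 2 and 4 turned was 0.11 (adjusted p 0.81) and that of the haploid and pheromone list -0.19 (0.265).

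Of 37 genes of meiosis and spore formation 30 had positive means, 3 were called, all positive, and 11 passed when adjusted over the list alone. The called genes were the spore kinase gene SPS1 at 1.16 ± 0.08, the spore wall gene DIT1 at 0.92 ± 0.15 and the spindle pole gene SPO21 at 0.67 ± 0.16 (SD, n = 4). The list mean of 0.33 ± 0.40 (camera adjusted p 9.62e-06, with the pair term 1.89e-05, and 0.626 with an estimated correlation) came from arrays 2 and 4, at 0.67, against -0.01 on arrays 1 and 3. The list passed in the opposite direction with the signs of arrays 2 and 4 turned, at -0.34 (adjusted p 0.000252). The 54 members of the subtelomeric PAU, COS, DAN, TIR, AAD and YRF1 families, whose copies can share probes, had a mean of 0.20 ± 0.14, with 0.08 and 0.32 in the pairs (adjusted p 4.15e-05, with the pair term 9.61e-05, and 0.626 with an estimated correlation). DAN1 was called at 0.97 ± 0.24 and TIR3 at -0.64 ± 0.13, and the same number, 1 positive and 1 negative, passed when adjusted over the list alone, and with turned signs the mean was -0.12 (adjusted p 0.363).

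**Figure D3:**
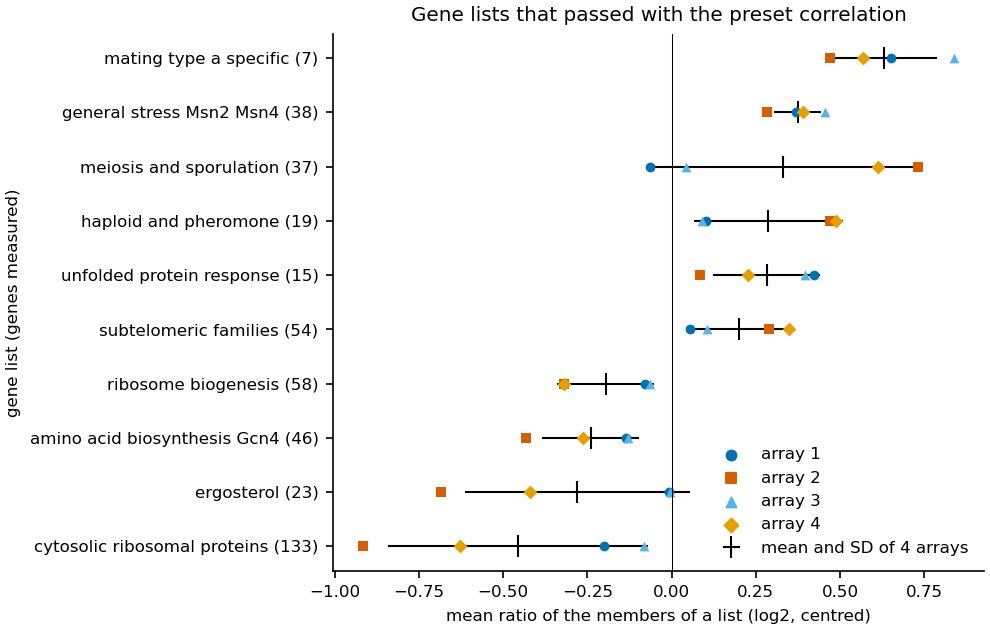
The mean log2 ratio of the members of each list is shown per array (coloured symbols) with the mean and SD of the 4 arrays, for the 10 lists that passed with the preset correlation. Every list shown but meiosis has means of the same sign on all 4 arrays, though ergosterol is near 0 on arrays 1 and 3 (-0.01). The meiosis mean is -0.01 over arrays 1 and 3 and 0.67 over arrays 2 and 4.

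Genes described in older work as having a functional Abf1 site, a list that counts ABF1 itself, missed the threshold over the 4 arrays and passed without ABF1. Of 25 genes 19 had negative and 6 positive means, with a list mean of -0.11 ± 0.14 (SD of 4 array means) and a median of -0.24 (camera adjusted p 0.0532, and 0.626 with an estimated correlation). Without ABF1 the mean of the other 24 was -0.18 ± 0.15, with -0.06 on arrays 1 and 3 and -0.30 on arrays 2 and 4 (adjusted p 0.0157, and 0.626 with an estimated correlation), a fit chosen after the values were seen. With the signs of arrays 2 and 4 turned the mean of these 24 was 0.12, and they did not pass (camera adjusted p 0.147). ABF1 was called positive and ARO3 negative, and 3 positive and 2 negative genes passed when adjusted over the list alone. The list shares RPL2A, RPL2B, RPL3 and RPS28A (-0.39, -0.64, -0.50 and -0.38) with the cytosolic ribosomal proteins. It shares ARO3, ILV1 and HIS7 (-1.13, -0.40 and -0.40) with amino acid synthesis. Both of those lists passed with negative means. With meiosis, which passed with a positive mean, it shares HOP1 and SPR3. The list was not tested without the shared genes. The spore gene SPR3 had 1.17 ± 0.52 and the ribosomal protein gene RPL2B -0.64 ± 0.37, and neither was called. For the 25 genes the adjusted p was 0.0228 with the term for the pair of arrays, 0.0276 on ranks, 0.0415 without the length trend, 0.0266 without array 1 and 0.026 without array 3, and the mean was 0.00 on arrays 1 and 3 and -0.21 on arrays 2 and 4. Of 20 silencing factors only ABF1 was called, and the list had a mean of 0.10 ± 0.35, with -0.20 and 0.40 in the pairs (adjusted p 0.816). Without ABF1 the other 19 had a mean of 0.02, with -0.29 and 0.33 in the pairs (camera adjusted p 0.881). RAP1 had -0.49 ± 0.25 and SIR2 -0.22 ± 0.24, and neither was called.

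Other lists did not pass with the preset correlation. Among the 65 mitochondrial ribosomal protein genes RSM27 (-0.99), MRPL28 (-0.87) and MRPL33 (-0.68) were called, with a list mean of -0.09 ± 0.16, 0.05 on arrays 1 and 3 and -0.23 on arrays 2 and 4, and a camera adjusted p of 0.0532. Among 24 subunits of RNA polymerases I and III the shared subunit gene RPB8 was called at -0.71 ± 0.15, with a mean of -0.12 ± 0.18, 0.04 and -0.27 in the pairs, and an adjusted p of 0.0532. With the signs of arrays 2 and 4 turned both of these lists passed with positive means, 0.14 (adjusted p 0.00153) and 0.16 (0.0119). Among 15 purine genes ADE8 (-0.91) and IMD2 (0.76) were called in opposite directions, with an adjusted p of 0.764. In fatty acid and phospholipid synthesis INO1 and CHO1 (-0.83) were called in opposite directions, with a mean of -0.09 ± 0.18 (adjusted p 0.254). MET13 was called at -0.80 ± 0.18 among 20 methionine and sulfur genes (adjusted p 0.242), ARN2 at 0.91 ± 0.29 among 17 iron genes (adjusted p 0.903), and LEU2 alone among 12 strain marker genes (mean 0.22 ± 0.08, adjusted p 0.083), where URA3 had -0.04 ± 0.39.

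Lists without a called member were glycolysis (mean -0.17 ± 0.36, camera adjusted p 0.083, 0.0481 with the pair term, and 0.831 with that term and an estimated correlation), the proteasome (0.08 ± 0.29, 0.412), respiration (0.03 ± 0.34, 0.877), the tricarboxylic acid cycle (-0.02 ± 0.14, 0.816), the phosphate regulon (0.01 ± 0.08, 0.764) and cell wall stress (0.01 ± 0.13, 0.646). The same held for histones (0.10 ± 0.37, 0.706), secretion (-0.04 ± 0.07, 0.519), replication origin factors (-0.06 ± 0.20, 0.412) and the genes of the cell cycle phases G1/S (0.04 ± 0.30, 0.855), G2/M (-0.07 ± 0.21, 0.174) and M/G1 (-0.09 ± 0.10, 0.328). The means on arrays 1 and 3 and on arrays 2 and 4 had opposite signs in 10 of these 12 lists: glycolysis 0.10 and -0.44, the proteasome 0.33 and -0.16, respiration 0.32 and -0.25, the tricarboxylic acid cycle 0.08 and -0.12, the phosphate regulon 0.04 and -0.01, histones 0.40 and -0.20, secretion 0.02 and -0.11, replication origin factors -0.22 and 0.09, G1/S -0.22 and 0.30, and G2/M -0.23 and 0.09. Glycolysis (0.27), the proteasome (0.24), respiration (0.29) and histones (0.30) passed with the signs of arrays 2 and 4 turned, with adjusted p of 0.000817, 5.44e-05, 4.3e-07 and 0.00495. The replication factor gene CDC6 had -0.57 ± 0.15 and an adjusted p of 0.0581.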

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

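No test of an explanation was run for the values here. The 126 items screened were 80 genes chosen by the fixed rule, of which some are not described in the text, 13 genes and probes named in the text outside that rule, and the means of 33 lists. In SPG4, a gene needed at stationary phase at high temperature, array 1 stood apart at 0.75, with 1.36 to 1.48 on the other arrays. In SVS1, a gene of vanadate resistance with peak expression in G1/S, array 2 stood apart at 0.18, with 0.65 to 0.68 on the other arrays. In MF(ALPHA)2, a gene for the precursor of the pheromone alpha-factor, array 2 stood apart at -0.89, with -0.52 to -0.46 on the other arrays. Chance gives such a gap in about 1 in 20 groups of 4 independent values, a share that need not hold here because the arrays fall into pairs. Of all 6189 features, 177, or 2.86%, had one, so 3 of 126 items do not stand out from the rest.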

How the results depend on the processing

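The term for the pair of arrays, the fits within pairs, turned signs, lists without ABF1, the fit without probes at a shared value, the removal of the length trend, and the estimated correlation and fry with a pair term were chosen only after the result was seen. No paired analysis was possible because the labels give 1 group, and each array itself sets mutant against wild type. Genes with an Abf1 site upstream were not tested, for want of a genome sequence. Genes near chromosome ends by distance were not tested either, although gene starts and ends were at hand. Over all alternatives, 838 of the values that answer a comparison kept their direction and their side of the threshold, 50 lost the call, 40 gained one, 48 counts moved and 14 changed sign. The sign was read as changed only where either value had passed. No value was missing, so the settings on the minimum number of arrays could change nothing, and each gave 38 of the 838. Medians kept the p-values of the means. Of 92 other genes and probes examined, 3 (SWI4, SIR4 and RIF1) changed sign outside the fit with turned signs. Unless a reason is given, the cause was not tested. Signal over background is not given in the sources used here, so its limit is unknown.

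The count of 200 calls (85 positive, 115 negative) was 98 (47, 51) with quantile normalization, 2 (1, 1) at an adjusted p below 0.01, 40 (19, 21) with treat, 2021 (1031, 990) with the pair term, 302 (1, 301) with turned signs, 2059 (961, 1098) on arrays 1 and 3 alone and 2602 (1463, 1139) on arrays 2 and 4 alone. It was 213 without centring or with equal spread, 234 with array weights (whose fit stopped before it converged), 199 with robust eBayes, 196 at 1.5-fold, 208 without the shared values and 246 without the length trend. With an array left out it ranged from 0 to 22, positive calls from 0 to 10 and negative calls from 0 to 12. With the pair term it was 1375 (693, 682), 1053 (534, 519), 1637 (845, 792) and 1360 (678, 682) without arrays 1, 2, 3 and 4. ABF1 kept 1.62 but missed an adjusted p below 0.01, and ranged from 1.5 to 1.82 with an array left out, where it lost the call each time, and from 1.37 to 1.86 with the pair term, where it kept it.

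With the correlation estimated per list 0 lists passed, without or with the pair term: cytosolic ribosomal proteins -0.46, ribosome biogenesis -0.20, general stress 0.37, amino acid synthesis -0.24, ergosterol -0.28, unfolded protein response 0.28, meiosis 0.33, a-specific 0.63, haploid and pheromone 0.29 and subtelomeric families 0.20 all lost the call at those unchanged means. With 3 residual degrees of freedom, or 2 with the pair term, that test has little power, so these losses do not show that a shift is absent. Few degrees of freedom are not the only reason for them. Without the pair term the estimated correlation was 0.68 for ribosomal proteins, 0.61 for ergosterol, 0.47 for meiosis and 0.26 for ribosome biogenesis. The preset 0.01 thus understated how far members of these lists vary together. With the pair term ribosome biogenesis had an estimated correlation of -0.0164, below the preset 0.01, and still a camera adjusted p of 0.614. Fry asks whether the members of a list shift from 0, whereas camera sets them against all other features. Calls lost or gained between fry and camera thus answer different questions. With fry 4 lists passed. The calls of ribosomal proteins (-0.46), ribosome biogenesis (-0.20), amino acid synthesis (-0.24), ergosterol (-0.28), unfolded protein response (0.28), meiosis (0.33) and haploid and pheromone (0.29) were lost and strain markers (0.22) gained one. With fry and the pair term 12 lists passed, among them ribosome biogenesis (adjusted p 0.00632), the unfolded protein response (0.0427), meiosis (0.0355) and haploid and pheromone (0.0269), which fry had lost without that term. There ribosomal proteins (-0.46), amino acid synthesis (-0.24) and ergosterol (-0.28) lost the call, and mitochondrial ribosomal proteins (-0.089), RNA polymerases I and III (-0.12), alpha-specific genes (0.35), strain markers (0.22) and secretion (-0.042) gained one. On ranks the reported targets (-0.11), RNA polymerases I and III (-0.12) and glycolysis (-0.17) passed. With the pair term the reported targets (-0.11) and glycolysis (-0.17) passed. Haploid and pheromone genes missed the threshold without centring (0.29) and without shared values (0.27). Mitochondrial ribosomal proteins passed with array weights (-0.10), without shared values (-0.11) and without the length trend (-0.10), RNA polymerases I and III with array weights (-0.13), and the reported targets without the length trend (-0.11) and without ABF1 itself (-0.18).

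On arrays 1 and 3 alone ribosome biogenesis (-0.072), amino acid synthesis (-0.13), ergosterol (-0.0065), haploid and pheromone (0.10) and subtelomeric families (0.081) lost the call, the proteasome (0.33), respiration (0.32) and histones (0.40) passed, and meiosis (-0.011), SWI4 (-0.83), SIR4 (-1.54) and RIF1 (-1.39) changed sign. On arrays 2 and 4 alone the unfolded protein response (0.16) lost the call, the reported targets (-0.21), mitochondrial ribosomal proteins (-0.23), RNA polymerases I and III (-0.27) and glycolysis (-0.44) passed, and the proteasome (-0.16) and respiration (-0.25) changed sign. With an array left out, the means ranged from -0.18 to -0.063 for RNA polymerases I and III, -0.37 to -0.14 for ergosterol, -0.28 to -0.016 for glycolysis, 0.22 to 0.35 for haploid and pheromone, -0.14 to -0.042 for mitochondrial ribosomal proteins, -0.002 to 0.19 for the proteasome, -0.15 to -0.048 for the reported targets and 0.24 to 0.35 for the unfolded protein response, each with a change of call. With the pair term, the reported targets passed without array 1 (-0.10) and without array 4 (-0.14), and glycolysis without array 3 (-0.20) and without array 4 (-0.27).

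With the signs of arrays 2 and 4 turned, general stress (0.038), unfolded protein response (0.13) and a-specific genes (0.11) lost the call, and the proteasome (0.24), respiration (0.29) and histones (0.30) passed. Lists that changed sign were cytosolic ribosomal proteins 0.32, mitochondrial ribosomal proteins 0.14, ribosome biogenesis 0.12, RNA polymerases I and III 0.16, glycolysis 0.27, amino acid synthesis 0.11, ergosterol 0.27, meiosis -0.34, haploid and pheromone -0.19 and subtelomeric families -0.12. Of these 10 lists, 8 passed in the opposite direction, and the haploid and pheromone (adjusted p 0.265) and subtelomeric lists (0.363) did not pass. Genes that changed sign were PES4 -0.15, ABF1 -0.14, RNP1 -0.28, YER187W -0.34, ULI1 -0.29, SPG4 -0.20, PRO3 0.29, DUG1 0.28, IPP1 0.082, DSS4 0.19, YEN1 0.49, SEC53 0.35, HBS1 0.011, RPP1A 0.52, ARO3 0.22, RPP0 0.29, RPL9A 0.20, RSM27 0.31, MRPL28 0.013, MRPL33 0.070, NOP56 0.0099, CBF5 0.039, RPB8 0.10, TRP3 0.016, ARO4 0.19, ILV6 0.15, ADE8 0.13, ERG28 0.064, INO1 -0.20, CHO1 0.13, SWI4 -1.22, SPS1 -0.066, SPO21 -0.13, STE3 -0.083, AGA1 -0.17, DAN1 -0.20, SIR4 -1.55, RIF1 -1.46 and probe 3626 at -0.023. Of these SWI4, SIR4 and RIF1 were called with turned signs and the others were not.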

Other observations

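The tests of turned signs, other sign patterns, mating type, effects within 1 pair of arrays, lists without ABF1, cross-hybridisation and the direction of the ratio were chosen only after the result was seen, and so was the set of genes at chromosome ends, which took the place of a planned set by distance. Of the 10 outermost annotated genes at each chromosome end, 284 were measured, with a mean log2 ratio of 0.19, 12 of them called positive and 1 negative. Genes that have only a systematic name also leaned to positive ratios, with a median of 0.12 over 424 genes. The genes of the silencing factors RIF1 and SIR4 differed between the pairs of arrays, RIF1 with -1.02 and -1.75 on arrays 1 and 3 and 1.87 and 1.21 on arrays 2 and 4.

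The split of arrays 1 and 3 from arrays 2 and 4 covered 2271 features, 1074 higher in the former with a median gene length of 937.5 bp and 1197 higher in the latter with 1749 bp, against 1293 bp for the others. After the trend on gene length was removed 2247 features parted the arrays, 1811 of them also before, and without probes at a shared value the mean correlation between the pairs was -0.109, which argues against either as the whole cause. An opposite sign of arrays 2 and 4 as the only difference would turn the correlation between the pairs to about minus that within them, and its mean of -0.097, against 0.742 and 0.864 within, argues against it. Whether a turned sign plays a part beside other differences cannot be told apart from unrelated pairs, because 44 features had opposite signs between the pairs at 2-fold or more on all 4 arrays and 32 the same sign (exact binomial p 0.207, over features that are not independent), and a dye swap or an array batch, which the labels do not name, stays open and untested. Of the 8 sign patterns of the arrays, 2, the deposited one included, called at least as many features as the deposited signs, which called 200, the highest other being 302 for the pattern that follows the pairs, and 8 patterns are too few for a share below 0.05.

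The a-specific, alpha-specific and meiosis lists leaned to positive ratios, with medians of 0.51, 0.443 and 0.30. The meiosis median was 0.314 after the length trend was removed, and mean ratios hardly followed gene length (Spearman -0.039), which argues against that trend as the cause. Before removal the median lay above 99.99% of random lists of genes with only a systematic name. Those lists were drawn gene by gene, whereas the meiosis genes vary together (estimated correlation 0.47). That share thus does not decide on a shift common to poorly characterised genes. On arrays 1 and 3 the meiosis mean was -0.011 (camera p 0.537), so an effect of 1 pair of arrays may account for its shift, whereas the a-specific mean was 0.519 on arrays 2 and 4 (p 0.0135) and 0.744 on arrays 1 and 3 (p 0.00269), all with the preset correlation. The a-specific list did not pass with an estimated correlation (adjusted p 0.626) or with the signs of arrays 2 and 4 turned (mean 0.11, adjusted p 0.81). Strains of different mating type on the 2 channels would give the a-specific and alpha-specific medians opposite signs, and both were positive, at 0.51 and 0.443. The alpha-specific mean was positive in both pairs of arrays, 0.18 and 0.53. This does not settle it, because the 4 alpha-specific genes go both ways, 3 positive and 1 negative. That list also did not pass (camera adjusted p 0.254). The contrast of mutant and wild type stays open and untested as a biological explanation.

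The shift of the outermost genes had a camera p of 6.98e-07, and 0.0177 with an estimated correlation. It is a hypothesis from these data that ratios are more positive near chromosome ends. The mean was 0.186 without the listed multigene families and 0.193 ± 0.022 (SE over 217 genes) for those with a standard name, which argues against copies in these families and poor characterisation as the whole cause, whereas 100% of random sets of other genes with only a systematic name lying lower decides nothing, since sets of 284 from 357 genes hardly vary around their mean of 0.097. On arrays 1 and 3 the mean was 0.031 (p 0.0641) and on arrays 2 and 4 0.346 (p 4.24e-07), so an effect of 1 pair of arrays may account for it. The difference between the mutant and wild type stays untested as an explanation.

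Neighbouring genes hardly resembled each other in mean ratio, with a Spearman correlation of 0.0266 across gene pairs, and divergent neighbours, which share a promoter region, exceeded other pairs by 0.034 (permutation p 0.299). The difference between the pairs of arrays correlated more, at 0.164. An effect of the position on the plate or array may account for this if that difference holds no contrast of mutant and wild type. A turned sign of arrays 2 and 4 would put that contrast into it, and positions themselves were not tested. The genes reported with an Abf1 site had a mean of -0.108 (camera p 0.021, and p 0.269 with an estimated correlation), with 0.00 on arrays 1 and 3 and -0.21 on arrays 2 and 4. Without ABF1 itself, which that list counts, the mean was -0.18 (camera p 0.00477, and p 0.215 with an estimated correlation), with -0.06 on arrays 1 and 3 (p 0.569) and -0.30 on arrays 2 and 4 (p 0.00137). A ratio of mutant over wild type would give a negative mean if Abf1 activates these genes, but the shift was past the threshold on arrays 2 and 4 alone and not with an estimated correlation. The list also shares members with the lists of ribosomal proteins and amino acid synthesis, whose means were negative. With the signs of arrays 2 and 4 turned, the mean without ABF1 was 0.12 (camera adjusted p 0.147). The direction thus stays unsettled.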
